A study of Glycine max with 6 samples.

How the data were processed

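Embryos were dissected from soybean seeds of 200 to 250 mg, crosslinked for 10 min in 1% formaldehyde and sonicated to chromatin fragments of 100 to 500 bp, per the labels' protocols. Chromatin was precipitated with antibodies raised against peptides at amino acids 103 to 117 and 275 to 289 of GLYMA.13G153200. The labels number the antibodies 1 and 2 without saying which peptide each number stands for, and the protocol lists 2 µg of the antibody to the first peptide and 3 µg of that to the second. Libraries were amplified with 15 PCR cycles. The labels call the replicates biological, with 2 per antibody and 2 for the input. The input libraries entered here only through the background in the values of the peak lists, and their own data were not analysed here.

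Reads were mapped with Bowtie 0.12.7 and peaks were called with MACS3 (no version given), per the submitters' processing notes. The deposited names give a q-value threshold of 0.01 and show that peaks were called for each library separately, with no pooling of replicates. The genome build, the annotation and the peak caller's options are not given in the sources used here. Each deposited list gives a start, an end and a summit position for every peak. The fold enrichment at the summit is a ratio of the ChIP signal to the local background expected from the control, as the authors' peak caller gave it. The significance is the deposited −log10 p and −log10 q of each peak. The deposited score is 10 times the −log10 q truncated to a whole number and was not used further. Fold enrichment and −log10 q are each peak's own values as the authors' peak caller gave them. They were used to describe, rank or filter peaks within a list, to compare the ranks of shared regions between lists and, for fold enrichment with −log10 p, to recover fragment numbers. Median fold enrichment at the shared regions is set side by side between libraries as a description, since each value is relative to its own library's background. It is also set against the peak numbers, for weaker enrichment as a candidate explanation of them. Starts were converted to count from 1.

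The numbers of peaks of at least 5 in −log10 q were 11802, 26970, 22405 and 34549 for antibody 1 replicates 1 and 2 and antibody 2 replicates 1 and 2, and those of at least 10 were 9056, 20448, 16866 and 24873. Library totals were not used here, and the depth was recovered from the deposited values. Fold enrichment was taken as the summit pileup plus 1 over the expected background plus 1, and −log10 p as the Poisson tail beyond that pileup, and both equations were solved for the pileup and the background of each peak. In replicate 2, 99.9% of the peaks of either antibody had a solution with a whole pileup (tolerance 0.02). In replicate 1 only 6.30% and 3.28% had one, and the pileups became whole (tolerance 0.01) in 100% of the peaks of fewer than 60 fragments with a single solution after division by 0.973 for antibody 1 and 0.749 for antibody 2. Such factors arise when a ChIP library is scaled down to its control before calling, which was assumed here and was not tested. The peaks checked for whole pileups after division numbered 3481 of 12047 for antibody 1 and 6377 of 23296 for antibody 2. The lowest background over the narrowest peak width, taken as the length of the extended fragment, gave 23.9 fragments per kb entering the call in both replicate 1 libraries, 21.2 in antibody 1 replicate 2 and 20.7 in antibody 2 replicate 2. On that assumption, before scaling down antibody 1 replicate 1 had 24.6 and antibody 2 replicate 1 had 31.9. Intervals on the number of fragments are exact Poisson intervals and those on shares are exact binomial intervals, at 95%, and both cover counting error only, since libraries amplified by PCR do not count independent molecules.

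Peaks of different libraries were called shared when their overlap covered at least 50% of the shorter peak, and connected peaks were joined into regions. The share of the shorter list that was shared was compared with 100 placements of that list at random positions of the same chromosomes, in one-sided permutation tests whose smallest p is 0.0099. Chromosome length was taken as the end of the last peak of any library. Placement within the same 1 Mb stretch was added after the data were examined. For chromosome position and spacing, regions on scaffolds were left out. The outer parts of chromosomes are the 25% of length at either end. The named regions are the 15 in all 4 libraries with the best value of the worst of their 4 within-list percentiles of fold enrichment, the ranking fixed before the data were examined for genes, applied here to regions. The top 10% of a list refers to fold enrichment within that list. The tests of chromosome ends, spacing and the strong regions of single antibodies were chosen after the data were examined, and the overlaps, the regions in all 4 libraries and the rank agreement were fixed before.

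Comparisons of promoters, DNA motifs and 19 lists of genes, and the naming of single genes with GLYMA.13G153200 among them, had been planned and were not made. The gene table used here is of assembly Glycine_max_v4.0, and the deposited peak positions did not line up with it. Of the shared regions, 15.5% lay within 500 bp of a gene end of that table, and 52 of 400 shifts of up to 200 kb gave at least as many (range 14.2% to 16.1%). On 4 chromosomes, 70 regions lay past the last gene of the table. No genome sequence was used here, and no coordinates were converted between assemblies.

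The procedure was tested on simulated lists made to resemble antibody 1 replicate 2. With 7200 of 12000 peaks (60%) planted as shared, 60.3% were recovered as shared, and a list placed at random shared 1.12% against 1.18% by chance (permutation p = 0.7723). Of 3000 regions planted in 4 lists, 2998 were found. Simulated whole pileups were recovered in 100% of peaks, and those scaled by 0.83 in 99.98%, with the factor found as 0.83. These pileups were drawn at random and not taken from a library, and the factors of 0.973 and 0.749 were not simulated. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Alternatives covered stricter thresholds, other overlap rules, lists of equal length, chromosomes without scaffolds, each library left out in turn, and crossed replicate numbers.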

Results

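Binding of the soybean protein GLYMA.13G153200 to chromatin was mapped by ChIP-seq (chromatin immunoprecipitation followed by sequencing) in embryos of Glycine max cultivar Williams 82 at mid-maturation. At this stage the cotyledons of the embryo fill with storage protein and oil. The peak names in the deposited lists call the protein ABI5, for ABSCISIC ACID INSENSITIVE 5, a basic leucine zipper (bZIP) transcription factor known in other plants for its part in abscisic acid signalling in seeds. Chromatin of 2 biological replicates was precipitated with 2 antibodies raised against different peptides of the same protein, which gave 4 ChIP libraries, and 2 input libraries of unprecipitated chromatin completed the 6 samples. The lists held 12047 peaks for antibody 1 replicate 1, 27768 for antibody 1 replicate 2, 23296 for antibody 2 replicate 1 and 36189 for antibody 2 replicate 2. The design asks where the protein was bound, and whether the sites recurred between biological replicates and between antibodies to different parts of the protein.

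The number of called sites differed 3.00-fold between the longest and the shortest list. Replicate 2 had 2.30 times as many peaks as replicate 1 with antibody 1, and 1.55 times as many with antibody 2. Antibody 2 had 1.93 times as many peaks as antibody 1 in replicate 1, and 1.303 times as many in replicate 2. With 2 libraries per antibody the smallest two-sided p of an exact permutation test of the antibodies is 0.333 without pairing. Paired by replicate number it is 0.5, so peak numbers were not tested between antibodies. The peaks were narrow, with median widths of 334 bp and 303 bp for antibody 1 replicates 1 and 2, and 360 bp and 298 bp for antibody 2. They covered 4.37 Mb, 9.14 Mb, 9.23 Mb and 11.9 Mb in the same order. The deposited fold enrichment at the summit, the position of highest signal in a peak, had medians of 5.32, 5.75, 5.23 and 5.57, and reached 50.3, 63.6, 39.2 and 66.6. The median peak rested on 45 fragments at its summit in antibody 1 replicate 1 (95% exact Poisson interval 32.8 to 60.2), 38 in antibody 1 replicate 2 (26.9 to 52.2), 58 in antibody 2 replicate 1 (44.04 to 74.98) and 35 in antibody 2 replicate 2 (24.4 to 48.7). These intervals cover counting error only.

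In the lists as deposited, nearly all sites of the shorter list recurred in the longer list of the second biological replicate with either antibody. With antibody 1, 11775 of the 12047 replicate 1 peaks overlapped a replicate 2 peak, which is 97.7% (95% exact binomial interval 97.5 to 98.0). With antibody 2, 21529 of the 23296 replicate 1 peaks did so, which is 92.4% (92.1 to 92.8). Random placement of the shorter list on the same chromosomes gave 1.23% for antibody 1 and 1.72% for antibody 2 (one-sided permutation test, p = 0.0099 for each, the smallest that 100 placements can give). Placement within the same 1 Mb stretch of the chromosome, which keeps the uneven density of sites, gave 2.16% and 3.02%. The longer lists held many further sites, since 42.5% of the antibody 1 replicate 2 peaks and 60.1% of the antibody 2 replicate 2 peaks overlapped a replicate 1 peak of the same antibody. Between lists limited to their 12047 peaks of highest −log10 q, the shared part was lower, 78.1% for antibody 1 and 78.6% for antibody 2.

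Most sites called with antibody 1 were also called with antibody 2, which called many further sites. In replicate 1, 11856 of the 12047 antibody 1 peaks overlapped an antibody 2 peak, which is 98.4% (98.2 to 98.6). In replicate 2, 24944 of the 27768 antibody 1 peaks did so, which is 89.8% (89.5 to 90.2). Of the longer antibody 2 lists, 50.6% of the peaks in replicate 1 and 68.9% in replicate 2 overlapped an antibody 1 peak. As deposited, 2060 joined regions had peaks in both antibody 2 libraries alone and 24 in both antibody 1 libraries alone. With each list limited to its 12047 peaks of highest −log10 q, these numbers were 515 and 323. Much of the difference between the antibodies therefore went with list length. Random placement of the antibody 1 lists gave 1.15% and 1.54% (one-sided permutation test, p = 0.0099 for each). The pairs that differed in both antibody and replicate number shared 98.0% of the antibody 1 replicate 1 peaks and 85.4% of the antibody 2 replicate 1 peaks. The summits lay close together as well, with a median distance of 21 bp between the antibodies in replicate 1 and 19 bp in replicate 2.

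Joining the overlapping peaks of the 4 lists gave 39947 regions, of which 11511 (28.8%) held a peak from every library. Random placement of the 3 longer lists gave a mean of 0.21 and at most 3 such regions (one-sided permutation test, p = 0.0099), or at most 5 with placement within the same 1 Mb stretch. The regions in all 4 libraries had a median width of 465 bp, and in 91.1% of them the 4 summits lay within 100 bp of one another. A further 7801 regions had a peak in every library except antibody 1 replicate 1, 5336 had peaks from both antibodies in replicate 2 alone, and 8978 had a peak in antibody 2 replicate 2 alone. Antibody 1 replicate 1 alone accounted for 59 regions, and 96.3% of its peaks lay in regions of all 4 libraries. The shortest list therefore set the number: without antibody 1 replicate 1, 19313 regions had a peak in the other 3 libraries. With each list limited to its 12047 peaks of highest −log10 q, 7861 of 17102 regions (45.97%) were in all 4. The other sets depended on list length as well. In the limited lists, 683 regions lacked antibody 1 replicate 1 alone, and 1333 had a peak in antibody 2 replicate 2 alone. Both antibodies in replicate 2 alone had 664, and both in replicate 1 alone had 813, against 48 in the full lists. Antibody 1 replicate 1 alone had 1229, against 59.

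**Figure D1:**
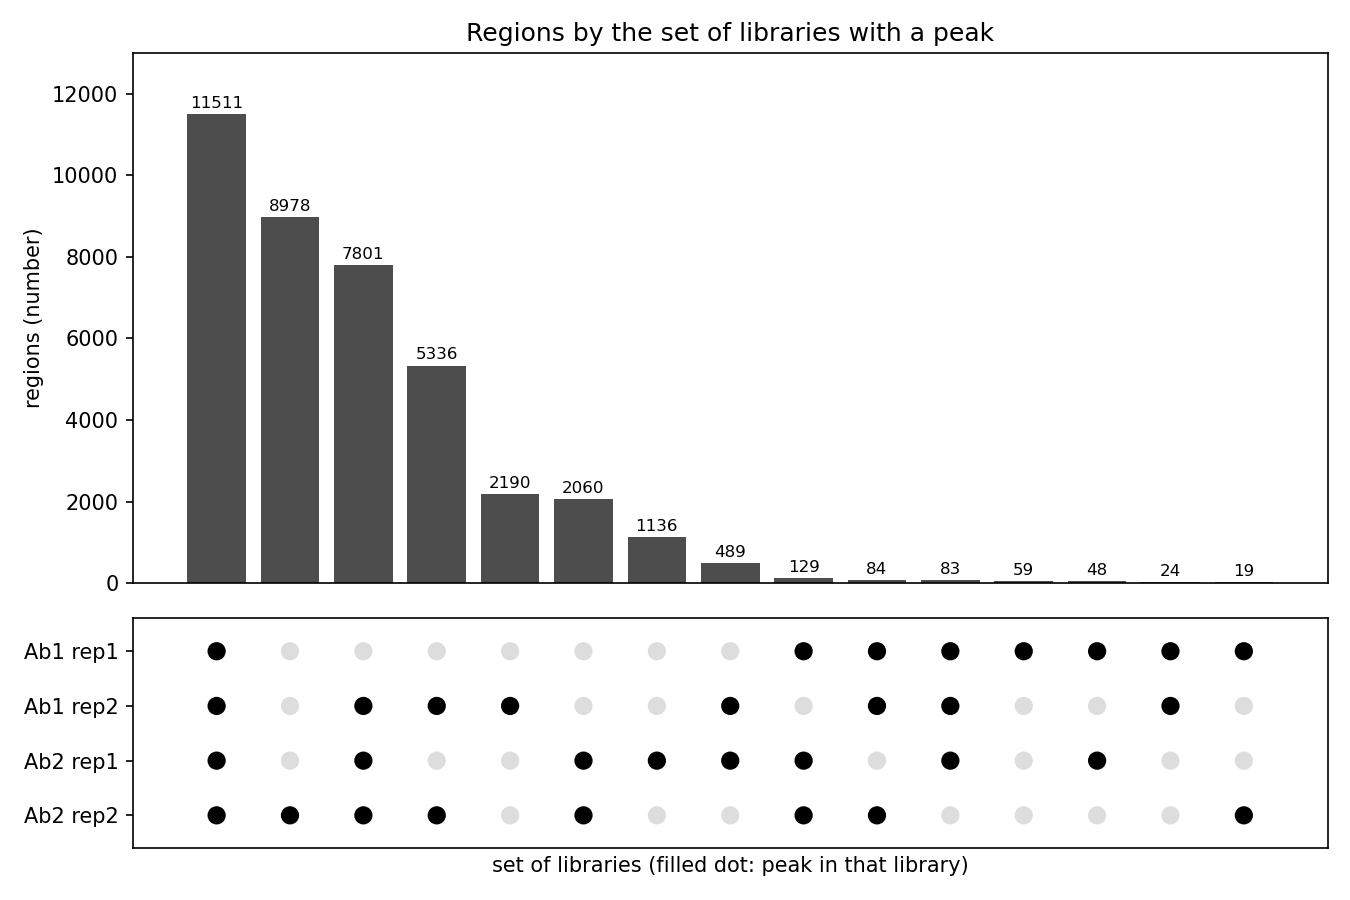
Number of regions (vertical axis) for each set of libraries with a peak in the region, where filled dots below each bar mark the libraries (Ab, antibody; rep, replicate). The tallest bar is the set of all 4 libraries with 11511 regions, followed by antibody 2 replicate 2 alone with 8978 and by all libraries except antibody 1 replicate 1 with 7801.

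Strongly enriched sites were found in all 4 libraries more often than weaker ones. Of the antibody 1 replicate 2 peaks in the top 10% of fold enrichment, 99.7% lay in a region of all 4 libraries, against 7.85% of those in the bottom 10%. The shares were 97.9% and 5.25% in antibody 2 replicate 1, and 89.2% and 3.29% in antibody 2 replicate 2. In antibody 1 replicate 1, the shortest list, they were 99.8% and 86.9%. The 8978 regions called in antibody 2 replicate 2 alone had a median fold enrichment of 4.23 in that library, and the regions in all 4 libraries had 9.16 there.

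**Figure D2:**
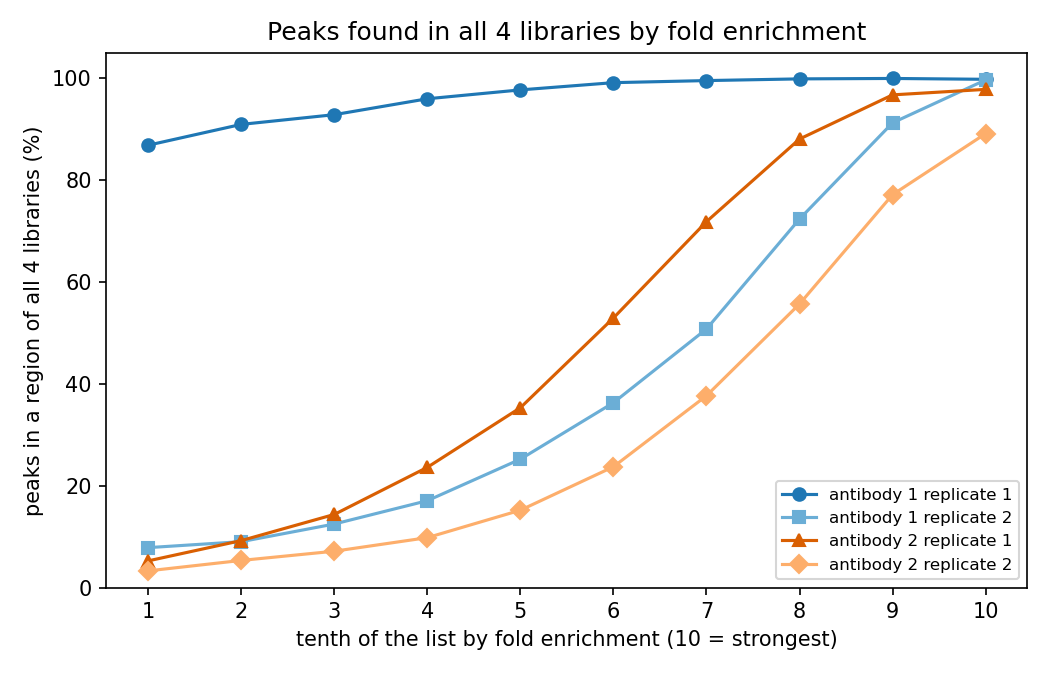
Percentage of a library's peaks that lie in a region with a peak in all 4 libraries (vertical axis), for each 10% of its list from the weakest (1) to the strongest (10) fold enrichment (horizontal axis), 1 line per library. The line for antibody 1 replicate 1 starts at 86.9%, and those of the other libraries start at 7.85%, 5.25% and 3.29% and end at 99.7%, 97.9% and 89.2%.

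The strongest region shared by the 4 libraries lay on chromosome 16 at 13050115 to 13051276, in the coordinates of the deposited lists. Its fold enrichment was 45.6 and 63.6 in antibody 1 replicates 1 and 2, and 37.4 and 66.6 in antibody 2 replicates 1 and 2. The next was on chromosome 11 at 2852694 to 2853868, with 40.0 and 52.0 for antibody 1 and 35.6 and 50.96 for antibody 2. On chromosome 2, the region at 11676089 to 11677273 had 38.3 and 48.5 for antibody 1 and 39.2 and 50.6 for antibody 2. On chromosome 5, the region at 2540764 to 2541871 had 36.5 and 44.0 for antibody 1 and 35.98 and 40.97 for antibody 2. The fifth, on chromosome 7 at 8460792 to 8461518, had 31.99 and 41.4 for antibody 1 and 35.6 and 47.1 for antibody 2. The other 10 of the 15 strongest regions lay on chromosome 18 at 55165916 to 55166727, chromosome 13 at 31638782 to 31639632 and at 13161642 to 13162496, chromosome 9 at 5709262 to 5710211 and at 34666401 to 34667267, chromosome 11 at 17933858 to 17934712, chromosome 3 at 45481540 to 45482274 and at 23958726 to 23959727, chromosome 19 at 6471175 to 6472168, and chromosome 4 at 6206225 to 6206858. Fold enrichment over the 15 regions and 4 libraries ran from 27.7 to 66.6, and the regions were 634 to 1185 bp wide. Ranking by −log10 q in place of fold enrichment kept 9 of the 15, and leaving out antibody 1 replicate 1 kept 12. Which genes lie at these positions was not analysed here, because the gene table used here does not line up with these coordinates.

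**Figure D3:**
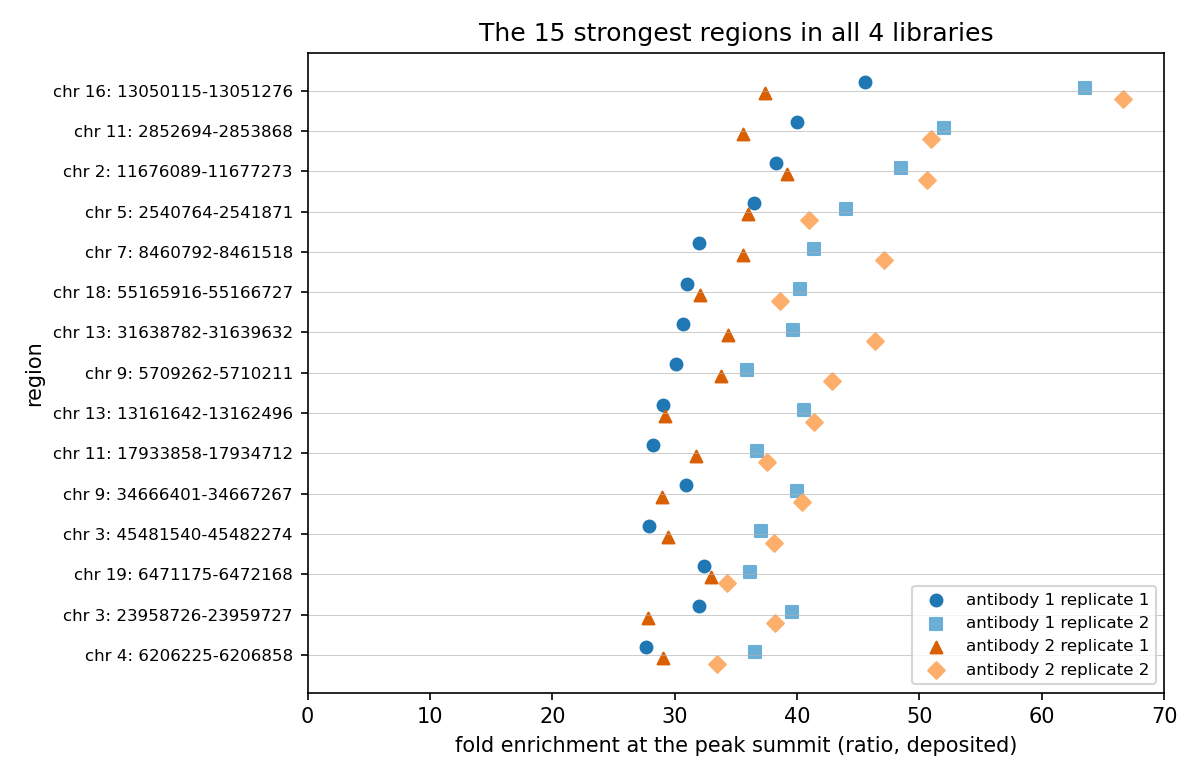
Deposited fold enrichment at the summit (horizontal axis, a ratio) of the 15 strongest regions in all 4 libraries (vertical axis, chromosome, start and end), 1 symbol per library. All values lie between 27.7 and 66.6, and the chromosome 16 region at the top has the highest value.

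Across the 11511 shared regions, libraries of the same replicate number ranked the sites most alike. Spearman's rho of fold enrichment was 0.857 between the antibodies in replicate 1 and 0.865 in replicate 2. Between the replicates it was 0.688 for antibody 1 and 0.722 for antibody 2, and the pairs that differed in both had 0.645 and 0.709. The mean of the same-number pairs exceeded that of the same-antibody pairs by 0.156. The excess was 0.0533 with −log10 q, and 0.0219 with the number of fragments at the summit recovered from the deposited values. These coefficients are across regions, which are not independent replicates.

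Sites strong with antibody 1 were all called with antibody 2, and a small set strong with antibody 2 had no antibody 1 call. All 1084 regions in the top 10% of both antibody 1 lists held a peak in both antibody 2 lists (0 without one, 95% exact binomial interval 0% to 0.340%). Of the 1907 regions in the top 10% of both antibody 2 lists, 1861 held a peak in both antibody 1 lists, 24 in 1 of them and 22 in neither, which is 1.15% for the last (95% exact binomial interval 0.724 to 1.74). These sets share regions, so the difference between their shares was not tested. The antibody 2 list was also the longer one in each replicate, and a missing call does not show that a site was unbound. In lists of equal length, 18 regions in the top 10% of both antibody 2 lists had no antibody 1 peak. The strongest of the 22 was on chromosome 4 at 7932679 to 7933331, with fold enrichment 29.7 and 45.3 in antibody 2 replicates 1 and 2. Next came chromosome 9 at 46261035 to 46261596 with 19.3 and 38.5, and chromosome 13 at 16380581 to 16381085 with 18.5 and 31.4. The 22 regions lay on 11 chromosomes and had median fold enrichments of 15.3 and 26.7. This set was chosen after its values were seen. The count rests on single libraries: without antibody 1 replicate 2, 44 regions lacked an antibody 1 peak, and without antibody 2 replicate 1, 198 of the 3608 regions in the top 10% of the remaining antibody 2 list lacked one.

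Binding sites were concentrated towards the chromosome ends. Of the 11449 shared regions on the 20 chromosomes, 8947 (78.1%, 95% exact binomial interval 77.4 to 78.9) lay in the outer 25% at either end, where uniform placement gave a mean of 50.02% and at most 51.1% (one-sided permutation test, p = 0.0099). This held on 19 of the 20 chromosomes, with up to 90.8% on chromosome 4. The exception was chromosome 13 with 43.6%, where the first 10 Mb held 14 shared regions (1.4 per Mb) and the remainder 831 (23.2 per Mb). Chromosome 13 also had the highest density of the 20, 18.4 regions per Mb (95% exact Poisson interval 17.2 to 19.7), and chromosome 1 the lowest, 9.17 (8.40 to 10.0). By 10% of chromosome length, density fell from 23.6 per Mb in the first part to 3.14 in the sixth and rose to 24.2 in the last. The densest 1 Mb stretch, 5 to 6 Mb on chromosome 15, held 54 regions, against a median of 8 over 956 stretches, of which 102 held none. The strength of the sites did not follow this gradient: median fold enrichment in antibody 2 replicate 2 was 9.15 in the outer parts and 9.17 in the inner parts, and in antibody 1 replicate 1 it was 5.43 and 5.54. Regions with a peak in 1, 2 or 3 libraries had 77.6%, 77.8% and 77.6% in the outer parts, so the pattern was not particular to shared regions. Uniform placement took no account of the density of genes or of mappable sequence, and neither was analysed along the chromosomes here.

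**Figure D4:**
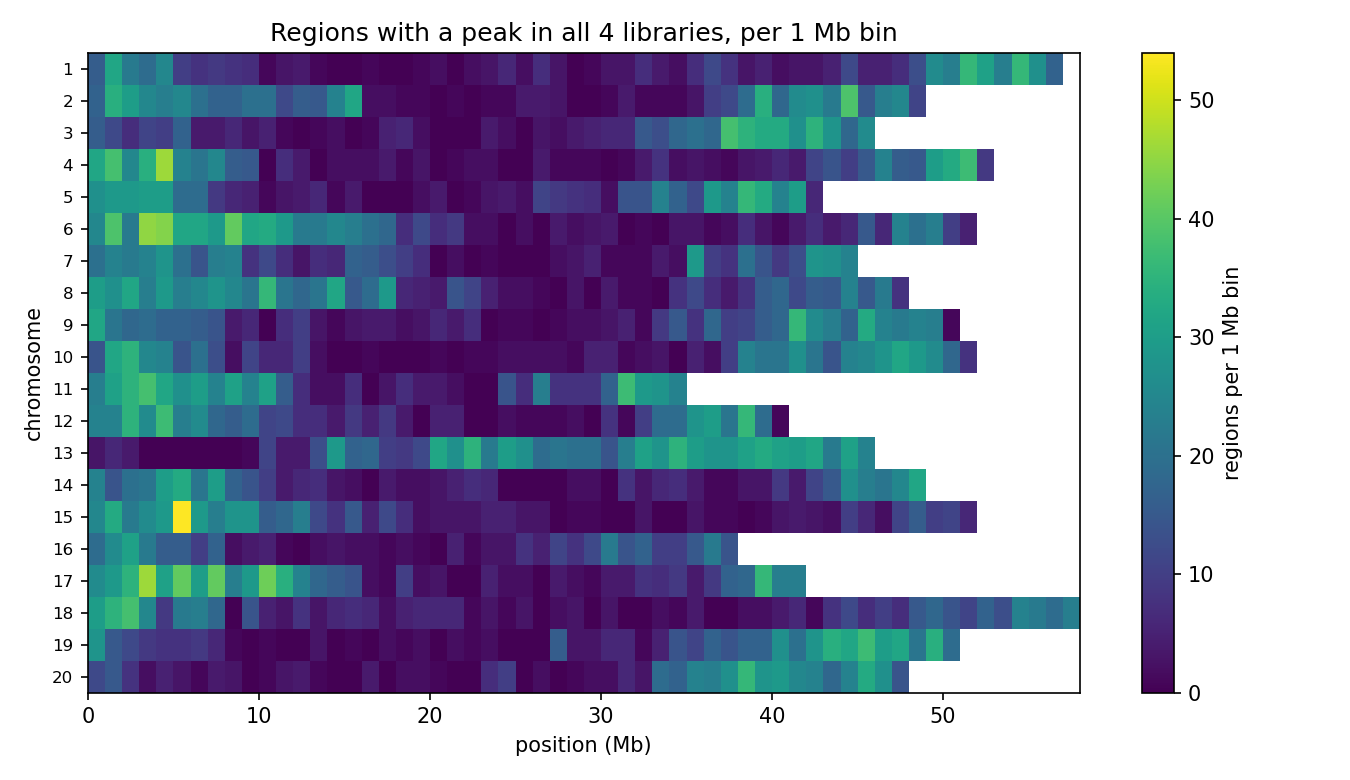
Number of regions with a peak in all 4 libraries per 1 Mb bin (colour), by position in Mb (horizontal axis) on the 20 chromosomes (vertical axis), with white beyond the last peak of a chromosome. Most chromosomes are densest towards both ends, and the first 10 Mb of chromosome 13 hold 14 regions.

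Shared regions also had neighbours at short distances more often than their local density gives. Summits of 675 of 11429 neighbouring pairs (5.91%) lay within 2000 bp, against a mean of 485.8 pairs and at most 547 with placement in the same 1 Mb stretch, a ratio of 1.39 (one-sided permutation test, p = 0.0099). Placement within the same 20 kb gave a mean of 581 and at most 646. Without antibody 1 replicate 1, which leaves more shared regions, the share was 9.50%. Pairs were most numerous at 1000 to 1250 bp, with 137 against a mean of 59.98. Within 1000 bp in all there were 204 pairs against a mean of 245.9 (one-sided permutation test, p = 1). This deficit lay at 0 to 250 bp, with 0 pairs against 62.8, and 250 to 500 bp, with 4 against 60.7, distances about as short as a region is wide. Placed regions could overlap one another, while overlapping peaks had been joined, so a deficit at these distances was built into the comparison. At 500 to 750 bp and 750 to 1000 bp there were 79 and 121 pairs against 60.4 and 61.7.

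**Figure D5:**
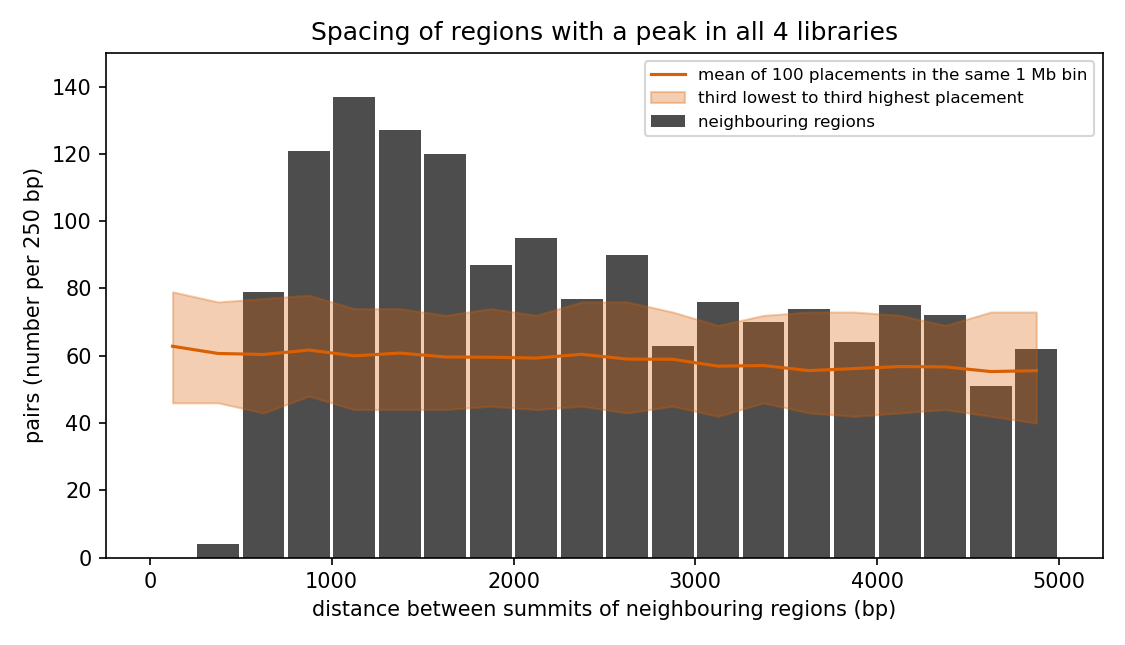
Number of neighbouring pairs of shared regions per 250 bp of distance between their summits (vertical axis) against that distance in bp (horizontal axis); bars are the observed pairs, the line is the mean of 100 placements within the same 1 Mb bin, and the band runs from the third lowest to the third highest placement. Observed pairs exceed the band from 500 to 2750 bp and in some bins beyond 3000 bp, with the highest bar, 137 pairs, at 1000 to 1250 bp.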

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

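The tests of chromosome ends, spacing, strong antibody 2 regions without an antibody 1 peak, the fragment number or −log10 q in place of fold enrichment, and placement within 1 Mb or 20 kb were chosen after the data were examined. The peak overlaps stayed above random placement under every alternative run, from 78.1% to 97.8% for antibody 1 replicates, 78.6% to 92.6% for antibody 2 replicates and 81.3% to 94.2% as the mean between antibodies, the lowest values being those of lists of equal length; the crossed replicate numbers gave 91.7%. The number of regions in all 4 libraries lay between 7861 (lists of equal length) and 11512 under the thresholds, overlap rules and list lengths run. Leaving out 1 library gave 11595 to 19313, the highest without antibody 1 replicate 1, whose list is the shortest, and 8239 to 8675 with lists of equal length. The share of regions in the outer 25% of chromosomes at either end stayed between 77.9% and 78.2%. The share of neighbours stayed above chance except within 1000 bp, where 1.78% of pairs fell below it. That deficit lay below 500 bp, about the width of a region. It was built into the comparison, since placed regions could overlap while overlapping peaks had been joined. No further cause was tested. Without antibody 1 replicate 1 the share within 2000 bp was 9.50%. The excess in rank agreement, 0.156, became 0.183 at −log10 q of at least 10, 0.191 with lists of equal length, 0.0533 with −log10 q and 0.0219 with recovered fragment numbers, and it kept its sign. Regions in the top 10% of both antibody 2 lists without an antibody 1 peak numbered 22, and 18 with lists of equal length. They became 34 with reciprocal overlap of 50% and 36 with summits within 100 bp, since both rules join fewer peaks. When 1 library was left out they numbered 23 to 198. Of 98 alternative values, 87 kept their direction and call or stayed within 1.5 times (counts) or within the bootstrap interval of the main value (rank agreement). Some of the 87 could not differ from the main value. Chromosome position and spacing already left out scaffolds, and a replicate block cannot change the ratio of peak numbers in this balanced design. Placement within 1 Mb leaves the observed overlap as it is and changes only the random values. With the replicate number as a block, also chosen after the data were examined, the ratio of antibody 2 to antibody 1 in peak number was 1.59, as without it, with a standard error on the log2 scale of 0.28 in place of 0.68; 2 pairs cannot give an exact two-sided p below 0.5. Overlaps and ranks belong to pairs of lists and had no such fit. The alternatives listed for promoters, motifs and gene lists were not run, since the comparisons themselves were not made. The median peak rested on 35 to 58 fragments at its summit, and how depth limits the calling of weaker sites was not tested; the lack of a call in 1 library does not show that a site was unbound there.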

Other observations

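The test of noise in single libraries and all tests of the peak numbers were chosen only after the result was seen. Several shared regions stood in groups. Joined at summit distances of up to 2000 bp, 1300 shared regions fell into 625 groups of 2 or more, and 6 groups held at least 4. The largest, on chromosome 11 at 31763902 to 31769326, held 5 regions, with fold enrichment of up to 20.1 and 21.9 in antibody 1 replicates 1 and 2 and 33.2 and 32.9 in antibody 2. Groups of 4 lay on chromosome 4 at 4062058 to 4065669, chromosome 5 at 26237742 to 26243170 and at 40535680 to 40539895, chromosome 12 at 38083900 to 38088527, and chromosome 17 at 15313402 to 15317908. The group at 26237742 on chromosome 5 reached 21.5 and 28.2 for antibody 1 and 23.8 and 27.9 for antibody 2.

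A few strong regions belonged to 1 biological replicate with both antibodies. On chromosome 7, the region at 44132356 to 44133698 had fold enrichment 50.3 with antibody 1 and 25.4 with antibody 2 in replicate 1, and the first of these is the highest value of its list; replicate 2 had no peak there. On chromosome 8, the region at 13066597 to 13067798 had 24.2 and 26.1 in replicate 1 alone. In replicate 2 alone, the region on chromosome 13 at 15513790 to 15514641 had 54.4 and 39.5, and that on chromosome 15 at 7659661 to 7661673 had 13.4 and 17.6. These 4 are all the regions in the top 10% of both lists of 1 replicate without a peak in the other, among 1184 such regions for replicate 1 and 2409 for replicate 2. They were singled out after their values were seen, and no explanation was tested.

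Fold enrichment ranked the shared regions more alike between antibodies of the same replicate number than between replicates of the same antibody, by 0.159 in mean rho over the 11468 regions with recovered values. The product of the same-number coefficients was 1.504 times that of the same-antibody coefficients (bootstrap interval 1.47 to 1.54). Noise of single libraries that lowers every pair of a library by the same factor gives 1, so noise of that kind alone is argued against for fold enrichment. This ratio restates the pattern and is no separate evidence, since both same-number coefficients exceeded both same-antibody coefficients. It was not computed for recovered fragment numbers, so such noise was not decided on for them. Among the 2297 regions of 435 to 497 bp the excess was 0.216. This does not decide on a difference in fragment length, since fragment length belongs to a whole library and remains at every region width. A candidate explanation that stays open is division by a background from an input library shared by both antibodies of a replicate, since the excess was 0.0219 (0.0170 to 0.0270) with recovered fragment numbers and the recovered background correlated at 0.884 between libraries of the same number and at 0.0899 between those of the same antibody. The interval of the remaining excess lies above 0, but it comes from resampling regions and does not cover differences between libraries. The same-number coefficients of fragment numbers were 0.882 and 0.869, and the same-antibody ones 0.840 and 0.867. Whether an excess remains beyond such differences was therefore not decided, and a difference between the embryos of the replicates was not tested.

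Peak numbers differed 3.00-fold between libraries. Between the shortest and the longest list, lower coverage entering the call is argued against by the background expected at the shared regions. In the library with the fewest peaks that background was 1.29 times that in the library with the most. That background also grows with the length of the extended fragment. Per kb, the same 2 libraries had 23.9 and 20.7 fragments entering the call, a smaller difference in the same direction. Within replicate 1 both libraries had 23.9 after the assumed scaling. Before it antibody 1 had 24.6 and antibody 2 had 31.9, in the direction of their peak numbers. Whether that depth plays a part was not tested. Weaker enrichment of the same sites stays open as a candidate explanation: the median fold enrichment at the shared regions was 5.46, 7.41, 8.70 and 9.16 in order of increasing peak number, a ratio of 1.68 between the ends. The median recovered summit pileup as scaled for the call, 44.7, 61.4, 59.0 and 58.0 in the same order, did not follow the peak numbers beyond the first library, and the same pileups over each library's lowest background, 8.04, 10.8, 13.5 and 14.2, did. Whether the antibodies or the chromatin preparations set that enrichment was not tested, with 2 libraries per antibody.

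The 22 regions in the top 10% of both antibody 2 lists lacked any antibody 1 peak. The recovered background of antibody 2 replicate 2 there was 0.960 of that at all peaks of its list (bootstrap interval 0.857 to 1.10, 21 regions). The lowest background of that list was 4.08 and its median 5.15, so a much lower ratio was not possible. Whether a low input background plays a part was therefore not decided. Missed detection in the antibody 1 libraries cannot be told apart from a difference between the antibodies. Of the 3608 regions in the top 10% of antibody 2 replicate 2, 198 (5.49%) were missing from antibody 1 replicate 2 and 46 (1.28%) from antibody 2 replicate 1, a ratio of 4.304, but this sets 1 library against 1 other, and antibody 1 replicate 1 has too short a list for the same comparison.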
